A study of Mus musculus with 2 samples.

How the data were processed

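The deposited data were aligned reads of 1 ChIP sample and 1 mock sample, called libraries here, from mouse E14 embryonic stem cells, and a list of peaks. Per the labels, both libraries were made with an anti-HA antibody, the first from cells carrying HA-tagged Nr5a2. The mock library's label names only embryonic stem cells. DNA from several immunoprecipitations was pooled before sequencing, per the labels' protocols. Each group therefore held 1 sample and no replicate by the labels.

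The authors deposited 7 alignment tables, 3 for the ChIP library and 4 for the mock library, each from 1 lane of a sequencing run. Each row of these tables was 1 aligned read of 35 bases with its chromosome, leftmost position, strand, match descriptor and an alignment score. The deposited score ran from 4 to 113 in every lane and was not used as a filter. The genome build was mm8, per the submitters' processing notes. The aligner, its filters and the peak caller are not given in the sources used here, nor is it stated whether the peaks were called against the mock library. The authors' peak list held chromosome, start and end for 3346 regions, without a score, height or p-value. Genome positions are printed counting from 1.

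The lanes came from 2 sequencing runs, called the first and the second run here. Lanes were treated as repeat sequencing of 1 library per group, since the labels give 1 sample each, and pooled; whether the mock lanes of both runs came from 1 library was not settled by the reads. The GC content of the reads differed between the runs in both libraries. It was 36.0% and 36.1% in the first-run ChIP lanes and 36.9% and 36.7% in the first-run mock lanes. It was 43.0% in the second-run ChIP lane and 44.2% and 44.1% in the second-run mock lanes. The runs also made up different parts of the 2 libraries, so values within each run are given beside pooled ones for reads in peaks and reads with the NR5A element. The window scan and the test of peak shares by chromosome were not repeated within each run.

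Reads on chromosomes 1 to 19, X, Y and M were kept, and 1 read was retained per chromosome, position and strand in each library. Reads were moved by 44 bp towards the centre of their fragment, from a lag of 88 bp between the strands inside the deposited peaks. This was the strongest lag from 60 to 349 bp; the strongest of all lay at 33 bp, close to the read length of 35 bases, and such lags were left out. Reads were counted within 250 bp of each peak's centre. Counts were compared with a one-sided exact binomial test given the library totals, with Benjamini-Hochberg adjustment over all peaks and a threshold of 0.05. The ratio of ChIP to mock was calculated per 1000000 distinct reads after adding 1 read to each count. Because the deposited peaks were presumably drawn from the same ChIP reads, these tests describe the listed regions and are no independent evidence that the list is right. They compare 2 libraries, not conditions. All intervals are 95% intervals and cover counting error only. Shares have exact Clopper-Pearson intervals and ratios of rates have log-normal Poisson intervals.

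The genome sequence of the build was not used here. The reference bases were instead rebuilt from the reads and their match descriptors. Different reads covered the same base 17840747 times around the peaks and flanks, with 0 conflicts. In this way 87.3% of the bases within 100 bp of the peak centres were recovered, against 31.8% in flanks centred 2 kb away. Flanks that came within 500 bp of a deposited peak were left out. Motif enrichment was therefore calculated as matches per 10000 covered positions on either strand, in place of the planned share of regions. It was tested with a two-sided Fisher's exact test on covered positions, adjusted over the 13 motifs fixed before the data were examined. Shares of peaks with an element were restricted to the 1741 peaks with at least 90% of the central bases covered. Positions and regions are not replicates. Covered flank positions are those that reads reached, so a flank position near weak binding was more often covered, and the enrichments given are relative to such positions.

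Windows of 200 bp with at least 10 ChIP reads were tested in the same way as the peaks. A window was called at an adjusted p under 0.05 and a ratio of at least 5. The scan was repeated with the libraries exchanged, and 10 times after dealing the pooled reads of each window outside the peaks at random to the libraries.

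The peak test was tested on simulated counts at the 3346 peaks, of which 200 were changed. It called 5 of 50 peaks with a simulated 3-fold difference, 19 of 50 at 5-fold, 38 of 50 at 10-fold and 47 of 50 at 20-fold. It called 1 of 3146 unchanged peaks. These rates hold for a list in which few peaks differ, where the adjustment is strict. In the data 3341 of the 3346 peaks passed the same threshold both with and without adjustment. The simulated rates therefore do not describe the test as applied to the deposited list. The motif scan recovered 200 of 200 elements planted in random sequences.

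Peaks were named by a rule fixed before the data were examined, as the 10 with the most ChIP reads per 1000000 distinct reads after subtracting the mock reads scaled alike. The gene parts of that rule, the 9 gene lists, the share of pluripotency genes with a peak nearby and the share of peaks close to a transcription start were not analysed here. The gene table at hand was of GRCm38.p6, and coordinates were not converted between builds. No gene is therefore assigned to any peak. The limit of 30 mock reads used to set peaks with many mock reads apart, the use of second-run mock reads only, a shift from the distance between the strand maxima, the random dealing of reads to libraries and to runs and the comparison of called with uncalled windows were chosen after the data were examined. Alternatives covered duplicates, scaling, window sizes, lanes and runs, thresholds, a stricter list of 1673 peaks and the motif settings. Calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.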

Results

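To locate the genomic sites bound by Nr5a2, an orphan nuclear receptor, in mouse embryonic stem cells, reads from an anti-HA ChIP of HA-tagged Nr5a2 were compared with those of a mock anti-HA ChIP. The HA tag is a short viral epitope for which an antibody exists. The ChIP library had 9096521 aligned reads, of which 8023427 were distinct, and the mock library had 13850266 and 13567301. Of the ChIP reads 5060333 came from the first sequencing run and 4036188 from the second. The mock library had 583046 reads from the first run and 13267220 from the second. The labels gave 1 library per group, so no difference given here has a replicate check.

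The 3346 deposited peaks (mm8) were narrow regions with many more ChIP than mock reads. Their median width was 443 bp, with a range from 185 to 5981 bp. A median of 22 ChIP reads (quartiles 18 and 30) lay within 250 bp of a peak's centre, against 4 mock reads (quartiles 2 and 5). Scaled to the library totals, the median ratio of ChIP to mock was 8.79, with quartiles of 6.20 and 13.5. By the exact binomial test with Benjamini-Hochberg adjustment, 3341 of the 3346 peaks had more ChIP than mock reads relative to the library totals. Of all peaks, 2918 (87.2%) had a ratio of at least 5, and 42 had a ratio under 2. Flanking regions 2 kb away, tested with adjustment within each side, gave 1 call of 3226 on 1 side and 5 of 3226 on the other. Their median ratio was 1.13. That adjustment was far stricter for flanks than for the peaks, nearly all of which passed. At an unadjusted p under 0.05 by the same binomial test, 130 and 121 flanks passed, against 3341 peaks.

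Forward-strand ChIP reads piled up to the left of the peak centres and reverse-strand reads to the right, with 125 bp between the maxima. In the 3267 peaks with fewer than 30 mock reads, the forward maximum was 0.159 reads per peak per 1000000 distinct reads in the 25 bp bin centred at -63 bp. The reverse maximum was 0.158 in the bin centred at 62 bp. The highest mock values were 0.00932 and 0.00907.

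**Figure D1:**
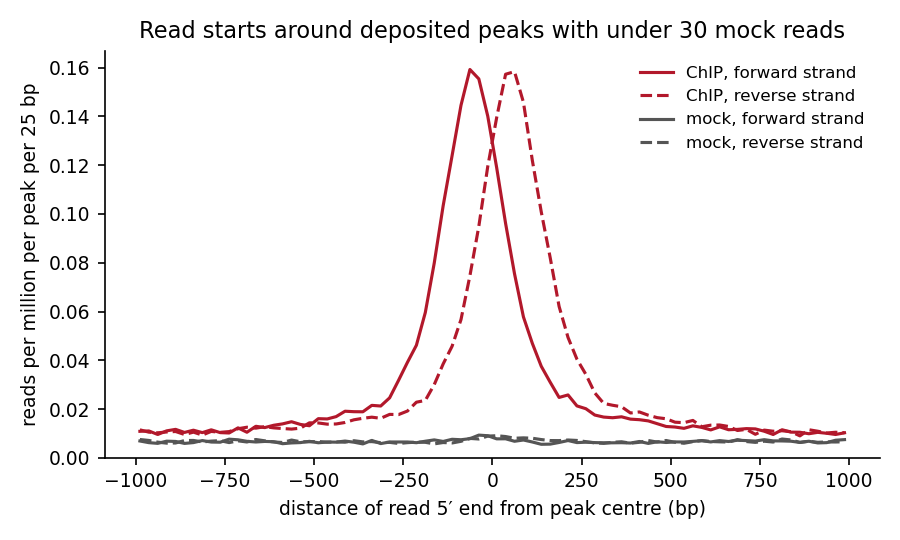
Read 5′ ends per 1000000 distinct reads per peak in 25 bp bins (y axis) against distance from the peak centre in bp (x axis), for 3267 deposited peaks with fewer than 30 mock reads. Solid lines show forward and dashed lines reverse reads of the ChIP (red) and mock (grey) libraries; the ChIP strands peak on either side of the centre at 0.159 and 0.158, far above the mock library.

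Peaks received 1.155% of the distinct ChIP reads (95% interval 1.147 to 1.162%) and 0.147% of the mock reads (0.145 to 0.150%), a ratio of 7.83. With repeated reads kept, the shares were 2.53% and 0.691% and their ratio was 3.67. With distinct reads the ratio was 10.0 within the second run and 2.56 within the first. A group of 79 peaks with 30 or more mock reads accounted for much of that gap between the runs. These peaks held 36.0% of the mock reads found in peaks and 9.41% of the ChIP reads, with a median ratio of 2.01. Their share of distinct reads was 0.488 times as high in the ChIP as in the mock library in the first run (0.463 to 0.515). In the second run it was 2.72 times as high (2.63 to 2.82). With 1 read kept per position and strand, counts cannot rise with depth where most positions are filled. The peak on chromosome 2 at 98462993 to 98463912 held 240 distinct first-run mock reads, 437 from the second run and 444 pooled. The ChIP was the deeper library in the first run and the mock in the second. This change of direction therefore cannot be told apart from depth. These 79 peaks held 1739 of the 2131 first-run mock reads in peaks. Without them the ratio was 11.8 (10.6 to 12.99) in the first run and 14.1 (13.9 to 14.4) in the second, against 11.1 with the runs pooled. In flanks of the other 3267 peaks the ratios were 1.28 and 1.19, and in those of the 79 peaks 0.978 and 1.31. Tested against the second-run mock reads, 2881 peaks were called with first-run ChIP reads and 3304 with second-run ChIP reads. The first-run reads of both libraries alone gave 0 calls by the binomial test, with 110 peaks at an unadjusted p under 0.05 and a median of 0 mock reads per peak.

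Among the 10 peaks with the most ChIP reads after subtraction of the mock, 4 stood clear of the mock library. The highest of these lay on chromosome 8 at 73625157 to 73625961, with 181 ChIP and 13 mock reads and a rate ratio of 23.5 (13.4 to 41.3). It was followed by a peak on chromosome 1 at 184337342 to 184338259, with 149 against 2 reads. A peak on chromosome 11 at 69380480 to 69381105 had 139 against 2 reads. The fourth, on chromosome 7 at 107027619 to 107028696, had 128 against 8 reads and a rate ratio of 27.1 (13.2 to 55.3). Each of the 4 held ChIP reads from both runs, but their order was not shared: the chromosome 8 peak had the fewest first-run reads, 38 against 58 to 66, and the most second-run reads, 151 against 75 to 112. Across the 3267 peaks with fewer than 30 mock reads, which are not replicates, the Pearson correlation of log2 scaled ChIP reads between runs was 0.232. Dealing each peak's reads to the runs at random gave 0.543 to 0.587 in 10 draws, so the runs differed by more than counting error. The GC content of the peaks went with this difference. Peaks of 40 to 42% GC together held 3743 first-run and 3730 second-run ChIP reads, and those of 50 to 52% held 3134 and 6423. How much of the low correlation this accounts for was not tested per peak. The other 6 of the 10 peaks held up to 444 mock reads each and had ratios between 1.69 and 2.34. The lowest ratio was that of a peak on chromosome 9 at 35054726 to 35055413, with 321 distinct reads in each library. That ratio came from the library totals alone, yet the binomial test called the peak. With 1 read kept per position and strand, ratios at such peaks do not measure how far the ChIP exceeded the mock. The 6 included the widest peak of the list, on chromosome 17 at 39450981 to 39456961, with 383 ChIP and 288 mock reads. They also included a pair on chromosome 2 at 98462993 to 98463912 and 98464399 to 98465008.

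The sequence recognised by NR5A receptors, YCAAGGYCA, was concentrated in the peaks. It occurred 27.7 times per 10000 covered positions within 100 bp of peak centres and 2.30 times in flanks 2 kb away, an enrichment of 12.04-fold (9.52 to 15.2; Fisher's exact test, adjusted p = 5.80e-204). Of the 1741 peaks with sufficient sequence, 759 (43.6%, 41.2 to 46.0%) held at least 1 such element, and 102 held 2 or more. With 1 mismatch allowed the share rose to 79.6%, while the enrichment fell to 4.34-fold. The same bases in reversed order, used as a composition control, were found 12 times in peaks and 7 times in flanks, a ratio of 1.02 (0.401 to 2.59). The share of peaks with the element did not rise steadily with peak strength, as ranked by the pooled runs. In quartiles of increasing ChIP signal among peaks with fewer than 30 mock reads, 39.6%, 48.2%, 42.5% and 44.9% of covered peaks held one. The density in the strongest quartile was 1.01 times that in the weakest (0.868 to 1.16). The enrichment over each quartile's own flanks was 14.9, 11.6, 7.99 (5.44 to 11.7) and 22.3 (11.9 to 41.9), with no steady order.

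**Figure D2:**
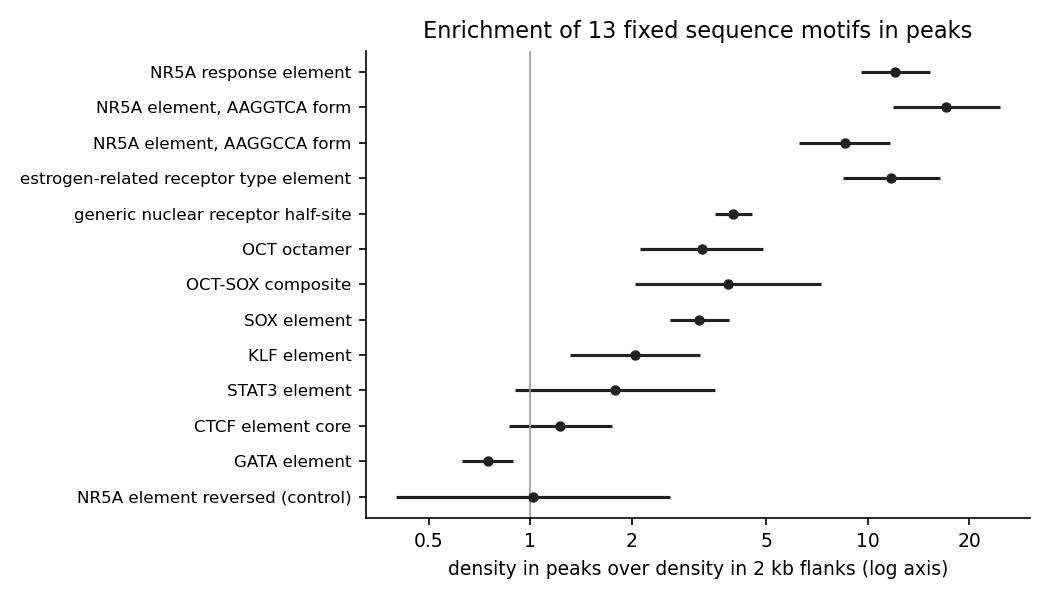
Density of 13 fixed motifs within 100 bp of peak centres divided by their density in flanks 2 kb away (log axis); points are ratios and bars 95% Poisson intervals. The AAGGTCA form of the NR5A element lies furthest to the right at 17.1, the estrogen-related receptor type element lies at 11.7 and the AAGGCCA form at 8.53, and the reversed control lies at 1.02.

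Elements lay close to the peak centres. Of 1811 elements within 250 bp of a centre, 55.7% were within 50 bp and 82.9% within 100 bp, with a median distance of 43 bp. Density reached 40.2 per 10000 positions in the central bins and was 3.70 in the outermost bin on the left. Both pyrimidines were found at the variable position. The form ending in AAGGTCA was enriched 17.1-fold (11.9 to 24.6) and the form ending in AAGGCCA 8.53-fold (6.26 to 11.6).

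**Figure D3:**
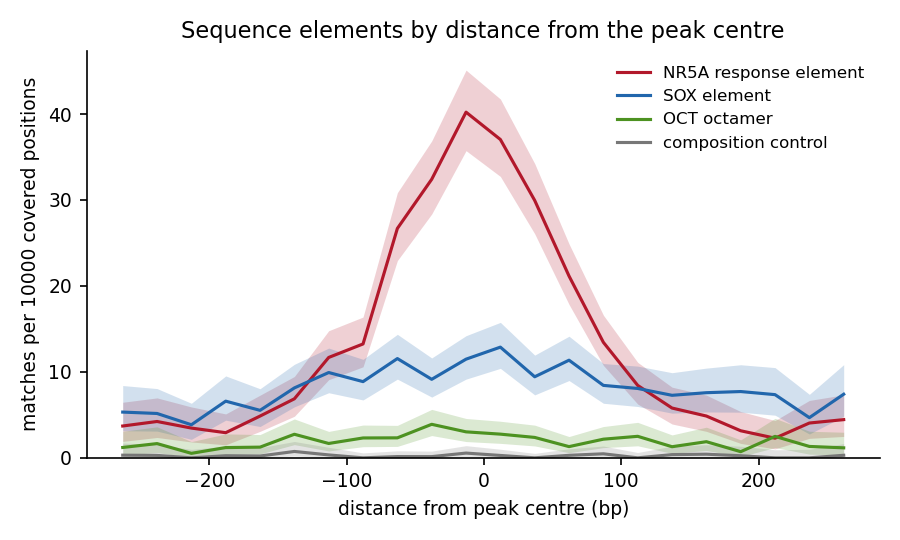
Matches per 10000 covered positions (y axis) in 25 bp bins by distance from the peak centre in bp (x axis), with exact 95% intervals as shading. The NR5A element rises to 40.2 at the centre, the SOX element and OCT octamer change far less, and the reversed control stays near 0.

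Single substitutions of TCAAGGTCA, counted from 1 at its 5′ end, showed which bases mattered for presence in peaks. The intact sequence was 22.4 times as dense in peaks as in flanks at 2 and 5 kb together (15.7 to 32.03). Each substitution of the first base was still enriched, from 10.1-fold for T1G to 15.5-fold for T1A. The same held for the last base, where A9T was enriched 10.4-fold (5.57 to 19.4). At the seventh base, T7C gave 10.8-fold, T7A 7.80-fold and T7G 4.71-fold. In contrast, none of the substitutions of the fifth base had an interval wholly above 1. G5A stood at 1.01 (0.538 to 1.89), G5T at 2.83 (0.996 to 8.02) and G5C at 2.355 (0.214 to 25.98). The last values rest on few matches, 12 in peaks for G5T and 2 for G5C. Substitutions of the other core bases went from 0.471 (0.148 to 1.502) for A4T and 0.550 (0.224 to 1.35) for A3C to 2.83 (1.35 to 5.91) for G6T, 4.26 (2.30 to 7.87) for A4G and 4.71 (1.00 to 22.2) for A3G. At the second base C2G was enriched 9.64-fold (5.15 to 18.0), below the intact sequence, whereas C2T stood at 1.44 (0.597 to 3.47). At the eighth base, C8T was enriched 8.98-fold (4.30 to 18.8), C8G 3.83-fold (1.73 to 8.45) and C8A stood at 2.83 (0.996 to 8.02).

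**Figure D4:**
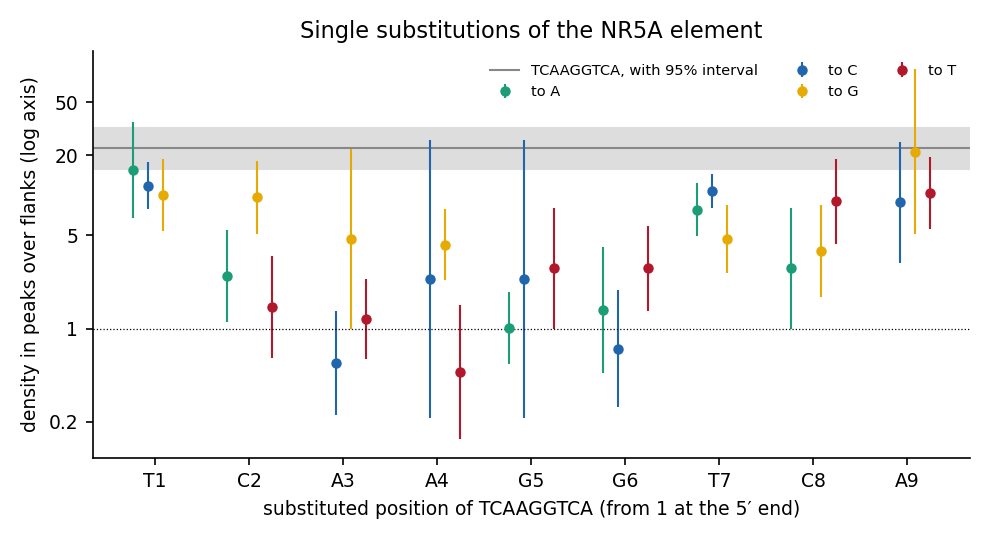
Density in peaks over density in flanks (log axis) for every single substitution of TCAAGGTCA, by position from the 5′ end and coloured by the new base, with 95% Poisson intervals; where no match was found, 1 was used. The grey band is the intact sequence at 22.4; substitutions of the first and last base stay high, and those of the AAGG core lie between 0.471 and 4.71.

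Some sites of factors that maintain the embryonic stem cell state, those of SOX, OCT and KLF, were also denser in peaks than in flanks. Their enrichment was lower than that of the NR5A element. The SOX element CWTTGTT was enriched 3.17-fold (2.59 to 3.88; Fisher's exact test, adjusted p = 1.36e-35) and the OCT octamer 3.22-fold (2.12 to 4.89; adjusted p = 2.25e-09). By the same exact test, the composite OCT-SOX site was enriched 3.86-fold (2.05 to 7.26; adjusted p = 2.67e-06) and the KLF element 2.04-fold (1.31 to 3.19; adjusted p = 0.00158). The composite OCT-SOX and CTCF sites were matched with 1 mismatch allowed here and below, the others with none. The site bound by estrogen-related receptors, which overlaps the NR5A element in sequence, was enriched 11.7-fold (8.43 to 16.3). Of its 730 matches in peaks, 610 were TCAAGGTCA, itself an NR5A element, so most of them were matches already counted above. By the same exact test, the ratio was 1.78 for STAT3 sites (0.901 to 3.53; adjusted p = 0.140) and 1.23 for CTCF sites (0.863 to 1.75; adjusted p = 0.282), and neither passed the threshold. GATA sites were rarer in peaks, with a ratio of 0.749 (0.629 to 0.892; Fisher's exact test, adjusted p = 0.00158). The median GC content was 46.8% in peaks with fewer than 30 mock reads and 40.6% in 5 kb bins of reads outside the peaks. The reversed control has the bases of the NR5A element, so the part of base composition in the ratios of these other sites was not tested. SOX sites were less frequent in peaks that held an NR5A element than in those without, at 14.8% of 759 against 20.7% of 982 peaks (odds ratio 0.664; Fisher's exact test adjusted over 7 motifs, p = 0.00700). Composite OCT-SOX sites showed the same difference, at 1.05% against 3.26% (odds ratio 0.316; Fisher's exact test, adjusted p = 0.00700). The OCT octamer was found in 3.95% and 4.07% of these peaks (odds ratio 0.969; Fisher's exact test, adjusted p = 1), and KLF, STAT3, CTCF and GATA sites did not pass either.

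Without reference to any peak, reads carrying the NR5A element made up a larger share of the ChIP library than of the mock library. They numbered 57.2 per 10000 distinct ChIP reads (56.7 to 57.8) and 29.9 per 10000 mock reads (29.6 to 30.2), a ratio of 1.91 (1.89 to 1.94). Within the first run the ratio was 2.28 (2.14 to 2.42) and within the second 2.43 (2.39 to 2.46), both above the pooled value. For the reversed control the ratios were 0.806 pooled, 1.148 (1.00 to 1.31) in the first run and 0.915 (0.875 to 0.957) in the second.

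A scan of 200 bp windows found further enriched places beyond the deposited list. Of 5691 windows with at least 10 ChIP reads, 4333 were called, of which 3608 overlapped deposited peaks and 725 did not. With the libraries exchanged, 456 of 1783 windows had an unadjusted p under 0.05 and 0 were called by the same binomial test. These 0 calls say little, because the mock library was deeper and a window without ChIP reads needed 23 mock reads for the first step of the adjustment, against 12 ChIP reads in the scan itself. When the reads were dealt to the libraries at random, at most 9 windows outside the peaks reached the p and ratio of the called windows in any of 10 draws. Such dealing repeats the assumption of the binomial test, so it covers counting error only. It cannot show calls that come from the different parts the runs, with their different GC content, made up of the 2 libraries. With adjustment over all windows that held a read, 18 windows outside the peaks passed the thresholds; with repeated reads kept 1608 did, and with 500 bp windows 2609 did. Of the 696 called windows more than 500 bp from any peak, 279 (40.1%, 36.4 to 43.8%) held an NR5A element. This compared with 131 of 756 windows (17.3%, 14.7 to 20.2%) that were tested there and not called, which held a median of 11 mock reads against 1 in the called windows. The element density was 2.53 times as high in the called windows (2.08 to 3.09).

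Peaks were spread over chromosomes 1 to 19 and X. Chromosome 11 held 251 peaks, 7.50% of the list (6.63 to 8.45%), whereas 5.62% of mock reads fell there (two-sided exact binomial test adjusted over 20 chromosomes, p = 1.28e-04). None of the other chromosomes passed the threshold. The X chromosome held 71 peaks (2.12%, 1.66 to 2.67%) with 2.52% of mock reads (exact test, adjusted p = 0.275). These mock reads came mostly from the second run. Of all aligned reads, 3.20 to 3.24% fell on X in the first-run lanes and 2.48 to 2.59% in the second-run lanes. On chromosome 11 the shares were 4.62 to 4.71% and 5.61 to 5.64%. The peak share of chromosome 11 lay above both, whereas that of X had an interval below the first-run shares only. The result for X therefore depends on the reference, and the test was not repeated by run.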

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

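The test of start-site sharing within the second run, the comparisons by the GC content of single reads, the limit of 30 mock reads and the counts of element reads outside the peaks were chosen only after the results were seen. The rule for reading the GC-matched ratio was also narrowed after its value was seen, so that a bound counts as passed only beyond the interval.

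Reads more than 1 kb from any deposited peak still carried the NR5A element more often in the ChIP than in the mock library, which drew attention to data outside the list. The ratio was 2.06 (1.93 to 2.19) in the first run and 2.16 (2.12 to 2.19) in the second. Of the ChIP reads with the element in excess of the mock share, 81.3% in the first run and 80.2% in the second lay outside the peaks. The mock share was taken separately from the reads outside the peaks and those within 1 kb of them. The 2 parts therefore do not sum to the excess over all reads. The reversed control gave 1.14 (0.997 to 1.31) and 0.907 (0.867 to 0.948) there. Reads placed on sequences other than the assembled chromosomes were also more frequent in the ChIP library, by 1.14 times in the first run (1.06 to 1.22) and 1.04 times in the second (1.01 to 1.08).

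The first pattern weighed was the difference between the runs in the share of ChIP reads that fell in peaks. Peaks with many mock reads were argued against as its source, since without them the second run still exceeded the first by 1.68 times. GC content accounted for a large part, as 5 kb bins of the same GC content as the peaks differed by 1.46 times between the runs. The remaining ratio was 1.151 (1.13 to 1.17): it excluded 1 and passed, by far less than its spread, the bound set beforehand for counting GC content out, and matching on the GC content of single reads left 1.102 (1.09 to 1.12). Whether GC content is the whole cause therefore stays open, and no biological explanation was tested, since the labels give both runs as 1 sample.

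The second pattern was that first-run mock and first-run ChIP lanes shared read start sites outside the peaks 2.69 times as often as mock and ChIP lanes of different runs, whereas the mock lanes of the first run shared them with those of the second 1.16 times as often, against 8.58 times within the first-run and 2.53 times within the second-run mock lanes and 19.1 times between the ChIP lanes of both runs. Carry-over of ChIP material as the whole cause would need 2.22% of the first-run mock reads and would bring the peaks with it. In the 3267 peaks with fewer than 30 mock reads, however, the first-run mock excess over flanks was 0.680% of the first-run ChIP excess (-0.458 to 1.82%). This was also below the bound of 3% set beforehand, and the second-run mock value was 1.148%. The comparison left out the 79 peaks with 30 or more mock reads, which held 1739 of the 2131 first-run mock reads in peaks, and says nothing about them. Second-run mock and ChIP lanes shared starts at 1.07 times the level across runs, but this cannot decide on a shared GC composition, which would itself give 1.00 to 1.16 times there. In the first run GC composition would give 1.59 times by the second-run mock reads, or 1.26 times with both runs as the reference. The cause stays open, carry-over and GC composition together included, as does whether the mock lanes of both runs came from 1 library, and no biological explanation was tested.

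The third pattern was the 79 peaks with 30 or more mock reads. Repeat copies merged in the genome build would collect reads in both libraries without an NR5A element. In these peaks 0 elements were found in 9674 covered positions, against 28.2 per 10000 in the other peaks. Counting 1 element in place of 0, the ratio was 0.0367 (0.00517 to 0.261). This is consistent with repeat-derived peaks, as a hypothesis: repeats were not identified by sequence, other regions without the element would give the same value, and no biological explanation was tested.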

How the results depend on the processing

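Alternatives that left out peaks with 30 or more mock reads, changed the base coverage needed for a peak, adjusted over all windows, used second-run mock reads only or took a shift of 62 bp from the strand maxima were chosen after the data were seen, and the others before. Of 86 alternative values for 7 results, 45 stayed within their limits, 41 moved and 0 changed direction. The enrichment of the NR5A element over flanks kept its direction and its side of the threshold under all 7 alternatives, from 4.34 to 15.4. The count of peaks with more ChIP than mock reads was between 2911 and 3343 in all alternatives but 1: the first run alone gave 0, where the mock library had 573956 distinct reads and a median of 0 reads per peak.

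The median ratio of ChIP to mock at peaks was 10.99 within 100 bp and 6.20 within 500 bp of the centre, and 11.5 in the stricter list. It was 1.33 in the first run alone, where most mock values rest on the 1 added read, and 11.3 in the second run alone, and 7.16 to 9.68 with each lane left out. The share of ChIP reads in peaks was 2.53% with all aligned reads, 0.746% within 100 bp, 1.41% within 500 bp, 1.145% without the shift, 0.781% in the stricter list and 1.05% without peaks of 30 or more mock reads. It was 0.951% in the first run, 1.499% in the second and 0.951 to 1.27% with each lane left out. Wider windows and longer lists hold more reads by construction.

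Enriched windows outside the peaks numbered 1608 with all aligned reads, 2609 with 500 bp windows, 18 with adjustment over all windows with reads and 0 in the mock over ChIP direction, where the deeper mock library left little room for a call. The share of peaks with an NR5A element was 30.2% within 50 bp, 53.9% within 250 bp, 79.6% with 1 mismatch, 49.6% for CAAGGYCA, 49.2% with every base covered and 38.8% over all peaks. The ratio of element reads was 1.87 with all aligned reads, 1.88 with second-run mock reads only, 2.28 in the first run, 2.43 in the second and 1.42 to 2.08 with each lane left out. It was lowest without the second-run ChIP lane, which sets ChIP reads of 1 run against mock reads mostly of the other. For the other values that moved, the cause was not tested. The alternatives set beforehand for the share of pluripotency genes with a peak nearby and for the share of peaks close to a transcription start were not run, as no annotation of the build was used here. The first-run mock depth limits any comparison within that run.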

Other observations

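The split of single reads by B1 context, the B1 share in flanks and the list of the strongest peaks with few mock reads were chosen only after the results were seen.

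Many NR5A elements in the peaks lay in sequence that resembles the SINE B1 repeat, a short interspersed element abundant in mouse DNA. Of 1478 elements within 100 bp of peak centres, 373 (25.2%, 23.0 to 27.5%) overlapped the B1-like sequence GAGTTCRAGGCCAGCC with up to 2 mismatches. Among the 73 elements in flanks 2 kb away the share was 30.1% (19.9 to 42.0%; Fisher's exact test, p = 0.338), a difference that did not pass the threshold. That this context is among the bound sites was a hypothesis taken from the peak sequences and tested on the same data. The context was 4.28 times as dense in peaks as in flanks (3.21 to 5.71). With A in place of R, however, the context itself holds the NR5A element TCAAGGCCA. Of its 439 matches in peaks, 398 held CAAGG. Its density in peaks is therefore no evidence beyond that of the element. An alternative is that B1 copies of any sequence gather in peaks. Copies without CAAGG had a ratio of 0.743 (0.459 to 1.201) and copies with it 8.41 (5.57 to 12.7), which differed by 11.3 times (6.01 to 21.3) and argues against that alternative. Elements in the B1-like context were enriched 10.1-fold (6.56 to 15.5) and elements outside it 12.9-fold (9.73 to 17.1). B1 copies that carry an NR5A element may therefore be among the sites bound by the tagged receptor. Whether they are favoured over other elements stays open. In peaks the 2 intervals overlapped, whereas the single reads below gave higher ratios in the B1-like context. The B1-like sequence holds the AAGGCCA form, while elements outside it include the more enriched AAGGTCA form. The forms were not compared separately.

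The same split appeared in single reads more than 1 kb from any deposited peak. Reads with an NR5A element in the B1-like context were 2.57 times as frequent in the ChIP as in the mock library in the first run (2.20 to 3.01) and 2.44 times in the second (2.35 to 2.52). Reads with the element in other contexts gave 1.96 (1.83 to 2.10) and 2.09 (2.05 to 2.13), below those in the B1-like context in both runs with separate intervals. Reads with the B1-like context and no CAAGG gave 1.02 (0.906 to 1.14) and 0.901 (0.872 to 0.932).

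Among the 10 strongest peaks with fewer than 30 mock reads, a list drawn up after the values were seen, 7 held at least 1 strict element within 300 bp of the centre and 3 held more than 1. The peak on chromosome 1 at 184337342 to 184338259 held 8, of which the first 3 were TCAAGGTCA at -145, -127 and -109 bp. The chromosome 8 peak at 73625157 to 73625961 held CCAAGGCCA at 61 bp and CCAAGGTCA at 74 bp. The peak on chromosome 7 at 107027619 to 107028696 held 0.

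After the core AAGGYCA was masked, some sequences of 8 bases were still denser in peaks with fewer than 30 mock reads than in flanks. TCAAGGAC was 7.31 times as dense as in flanks and TCTATTGT 7.50 times, with 199 and 129 matches in peaks. TCAAGGAC forms the first 8 bases of the T7A variant of the element, and others, such as CAAGGACA, also held CAAGG. Variants of the element thus remained after masking. The sequences were picked from all those of 8 bases by their excess and were not tested further.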
